A study of Mus musculus with 9 samples.

How the data were processed

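Cultured synovial fibroblasts from mouse paws were profiled by RNA sequencing in 9 libraries, 3 from naive paws, 3 from non-primed paws and 3 from primed paws. Per the labels' protocols, RNA was purified with a column kit and equal amounts went into a stranded mRNA library kit. Per the submitters' processing notes, the steps used cutadapt 2.5, STAR 2.5.4a, Subread 1.6.1 with featureCounts, DESeq2 and the GRCm38 genome. The annotation release, the strand setting of the counting and the settings of the transformation are not given in the sources used here.

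The authors deposited a single table of rlog values, which are on a log2 scale, for 47729 genes in all 9 libraries. The regularised logarithm scales each library for depth and draws the values of genes with few reads towards the mean of that gene, so differences of weakly expressed genes are understated on this scale. Read counts are not used here, so the depth of each library is unknown and no interval that needs a depth is given. The precision of each value is that of the spread between 3 libraries. In the table, 19972 genes stood at 0 in all 9 libraries and 27757 varied. Gene symbols came from a table of gene identifiers and names, which matched 47224 of the identifiers. Coordinates are those of GENCODE M21, which is on GRCm38.

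Groups were taken from the sample titles and the columns were matched to samples by their names. Tests were run on the deposited rlog values with limma 3.58.1 in R 4.3.3. Genes entered the tests when they varied and had a mean rlog of at least 3 over the 9 libraries, which left 15623 genes and removed 12134. A linear model with 1 mean per group was fitted to all 9 libraries, so that the 3 groups shared an estimate of the spread with 6 residual degrees of freedom. The 3 pairwise differences were tested two-sided with moderated variances that followed a mean-variance trend, and any difference among the 3 groups with the moderated F statistic. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene passed at an adjusted p below 0.05. Genes whose groups did not overlap were also counted, because an exact test of 3 libraries against 3 cannot give a two-sided p below 0.1.

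Before the data were examined, 50 gene lists were fixed for pathways, tissue functions and cell types that the cultures could hold. They comprised 804 genes, of which 803 were matched, 2 of them through synonyms, and 703 were tested. The 46 lists with at least 3 tested genes were compared with all other tested genes by camera, two-sided, with the preset correlation of 0.01 and adjustment over the 46 lists. An estimated correlation between the genes of each list was an alternative. The lists for MHC class II, lymphocytes, and neutrophils and mast cells had 2 tested genes each and that for Xist had 0, so they were not tested. Counts of list members are given over all genes tested and adjusted over the list alone.

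The genes named in the text follow a rule fixed before the data were examined. It takes, per comparison and direction, the 10 largest differences among genes past the threshold whose groups did not overlap and whose symbol was not that of a predicted gene. Where fewer than 10 passed, all that passed were taken, then the smallest p-values up to 5 in all, named as not past the threshold. From each list past the threshold it takes up to 4 members with the smallest p-values in the direction of the list and up to 2 that passed in the other direction. It adds 27 genes fixed in advance, of which 26 were tested and Il1b was below the filter. Other genes are named only where the text says so, and a few genes that the rule takes are not reported here. Values of H2 genes, Ifit3 and Gstm genes are uncertain where close copies share reads, as are those of overlapping and antisense genes, since the strand setting is not known.

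The comparisons of the injected groups with naive libraries share those libraries. Their agreement was given as the Pearson correlation and covariance of log2 differences across genes and as the overlap of calls. Each was set beside 100 simulations of unchanged groups with the observed spread of each group, and the overlap also beside that of independent lists. The simulations drew genes and libraries independently, without pairs.

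The design text says that primed and non-primed cultures came from different paws but not necessarily from different mice, and that the numbers 1 to 3 need not identify a mouse. The numbers were checked by correlating the deviations of libraries from their group means across genes. The correlation was 0.418 for primed 1 with non-primed 1, 0.608 for primed 2 with non-primed 2 and 0.100 for primed 3 with non-primed 3. By the rule that each of 3 pairs lies above 0.1, primed and non-primed libraries were taken as possibly paired. This entered only the alternative fits with a block and the reading of the regroupings. The last pair lies at that bound, and non-primed 3 had a higher correlation, 0.275, with primed 1. Naive libraries were not paired with the others, the correlation of naive 2 with non-primed 2 being -0.160. The pairing comes from these data and not from the design, and the model fixed in advance has no block.

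Alternatives fixed in advance were other filters on low values, other scalings, other prior variances, sample weights, a fit to the 2 compared groups alone, the replicate number as a block and leaving out each library. A block over primed and non-primed libraries alone, and the mean of the macrophage list as a covariate, were added after seeing the data. The procedure was tested on simulated data with the real means and moderated spreads of 15623 genes, in 10 data sets. Each gene had the same spread in all 3 groups and was drawn independently of the others. In the real libraries the spread differed between groups and genes of a list moved together. The shares below therefore show that the procedure works in that simpler setting and are not error rates of these data. For the comparison of non-primed with naive libraries with 200 changed genes per set, 19.4% of changes of 0.5 on the log2 scale, 68.7% of changes of 1 and 93.3% of changes of 2 were recovered, and 5.2% of calls were false. For primed against naive libraries, a glycolysis list shifted by 0.3 on the log2 scale was called in 10 of 10 data sets, with 4 calls of other lists in total.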

Results

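The series measured gene expression in cultured synovial fibroblasts, the connective tissue cells of the joint membrane, from paws of BALB/c mice. Monosodium urate (MSU) crystals, the crystals that deposit in gouty joints, were injected to inflame the paw. The 3 non-primed libraries came from right paws injected on day 9 only. The 3 primed libraries came from left paws injected on day 0 and again on day 9. The 3 naive libraries came from paws with no injection. The labels place RNA extraction at day 18 and give 5 passages of culture. Comparing primed with non-primed cultures asks what an earlier bout of crystal inflammation in the paw left behind, and comparing each with naive cultures asks what distinguishes cells from injected paws. Paw side coincides with priming, and no label names the animal behind a culture, so the p-values measure the spread between these samples only. All values are rlog values on a log2 scale, the depth of the libraries is unknown, and differences carry the standard error (SE) of the limma fit.

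The naive cultures differed from each other more than the injected cultures did. The median SD between replicates over 15623 genes was 0.22 in naive, 0.10 in non-primed and 0.14 in primed libraries. The first principal component held 38% of the variance and set naive 3 apart, and the second held 30.5% and placed naive 2 at its far end. Naive 3 had the lowest level of Prg4, the lubricin gene of the joint lining, at 8.34 against 11.04 in naive 1 and 12.01 in naive 2. Naive 2 had the highest level of Mmp3, a matrix-degrading protease, at 19.48 against 16.13 to 17.44 in the other libraries. The marker mean of macrophages was 7.07 in naive 1 and 6.84 in naive 3 but 9.04 in naive 2, and 8.80 to 9.97 in the 6 injected libraries. Vim, a member of the fibroblast list, was at 15.36 to 16.05 in all 9 libraries, which by itself does not show an equal share of fibroblasts.

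**Figure D1:**
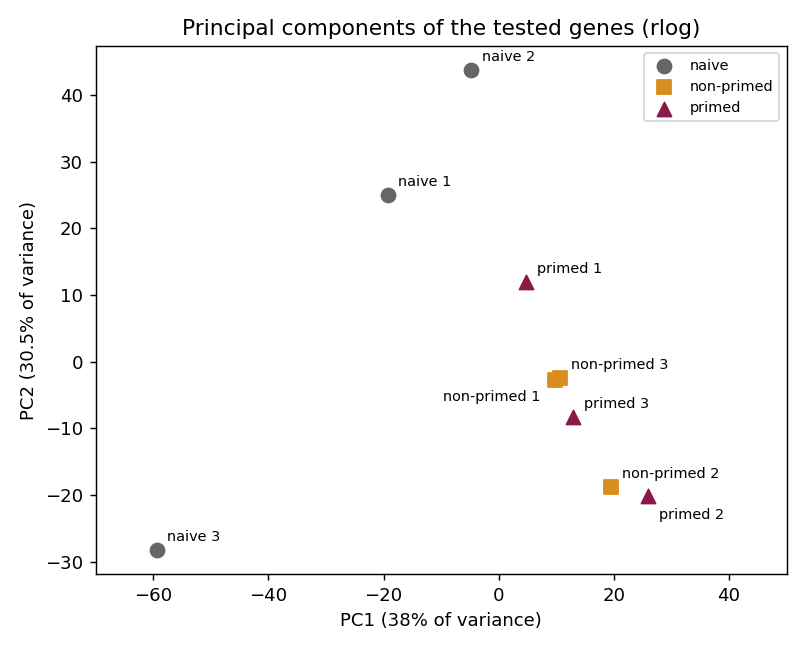
Principal components of the 9 libraries over the tested genes, with PC1 (38% of variance) on the x axis and PC2 (30.5%) on the y axis. Each point is a library, with colour and shape showing its group. Naive 3 lies at -59.4 on PC1 and naive 2 at 43.8 on PC2, while the 6 injected libraries lie between 4.82 and 25.9 on PC1.

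Cultures from paws injected a single time differed from naive cultures in 22 of 15623 genes, 18 higher and 4 lower (limma, adjusted p from 0.0303 upwards). The largest difference was in Esm1, a proteoglycan gene best known from endothelial cells (ENSMUSG00000042379, chromosome 13, 113209659 to 113218098), which fell from 9.53 ± 0.68 to 6.15 ± 0.45 (SD, n = 3), a difference of -3.38 (SE 0.36, adjusted p = 0.0303). Genes known to respond to low oxygen rose. Car9, a carbonic anhydrase (ENSMUSG00000028463, chromosome 4, 43506966 to 43513729), rose by 1.22 (SE 0.17, adjusted p = 0.0483) and Slc16a3, the lactate exporter, by 1.03 (SE 0.12, adjusted p = 0.0303). Bnip3, a mitophagy receptor, rose by 0.76, Pdk1, a kinase that limits entry of pyruvate into the mitochondrion, by 0.70, and Egln1, an oxygen sensor that marks HIF1A for degradation, by 0.51. The other leading rises were Perp at 1.73, Krt7 at 1.72, Aqp5 at 1.69, Cdh17 at 1.39, Pla1a at 1.22, Ccdc125 at 1.07, Arsi at 0.91 and Tmem45a at 0.87. Beside Esm1, the falls were Ltbp3, a binding protein of latent TGF-beta, at -0.71, Thbs3, a thrombospondin, at -0.69 and Slc25a12, a mitochondrial aspartate-glutamate carrier, at -0.46. All 22 genes separated the groups without overlap, as did 3417 (21.9%) of the tested genes, where chance gives 10%. Hif1a itself was 0.82 higher (SE 0.13) without passing the threshold (adjusted p = 0.0583).

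The number of these calls depended on single libraries, even on primed ones, which enter this comparison only through the shared spread and the filter. Naive libraries varied most, so the shared spread tends to make the SE of this comparison too small. The number was 0 without non-primed 1, non-primed 2, non-primed 3 or primed 2 and 1 without primed 3, but 355 without naive 2, 266 without naive 3, 83 without naive 1 and 48 without primed 1. It was 0 with no filter on low values or with the macrophage mean as a covariate, where Esm1 was at -3.76 (SE 0.50), Perp at 2.06 (SE 0.24), Bnip3 at 0.78 (SE 0.13) and Car9 at 0.89 (SE 0.18). It was 5 without a variance trend, 7 with the 2 groups fitted alone, 13 with a robust prior and 621 with sample weights. With the replicate number as a block 17 genes passed, 5 of them among the 22, and the calls of Esm1, Slc16a3 and Bnip3 (adjusted p = 0.0501 each), Pdk1 (adjusted p = 0.0647), Egln1 (adjusted p = 0.0744), Aqp5, Arsi, Ccdc125, Cdh17, Krt7, Ltbp3, Pla1a, Slc25a12 and Thbs3 were lost.

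**Figure D2:**
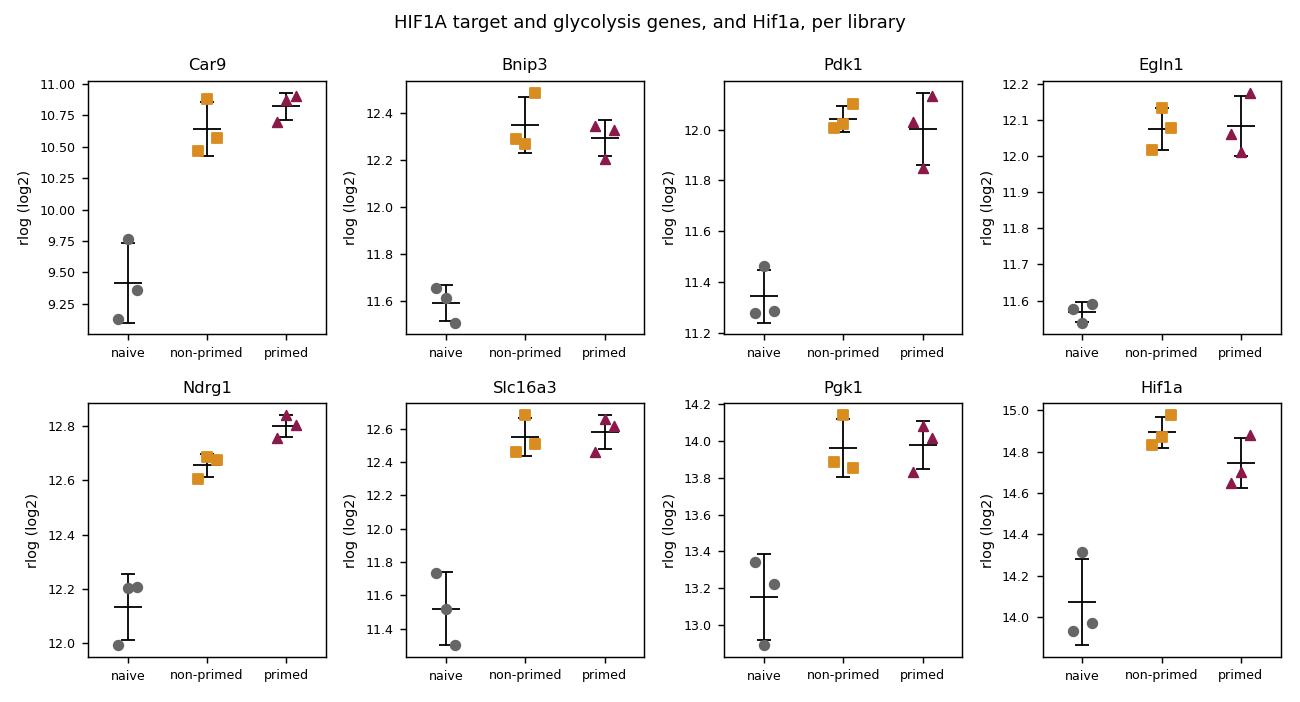
Rlog values (log2, y axis) of 5 HIF1A target genes, 2 glycolysis genes and Hif1a in the 3 groups (x axis). Points are libraries, with the mean and SD (n = 3) in black. For every gene shown, the 3 naive libraries lie below the 6 injected libraries. Car9 averaged 9.42 in naive, 10.64 in non-primed and 10.82 in primed libraries.

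As a group, the HIF1A target genes rose in non-primed over naive cultures (camera adjusted p = 2.44e-11, and adjusted p = 0.0139 with an estimated correlation). Their median difference was 0.51, with 19 of 20 members higher, 4 past the threshold over all genes and 11 adjusted over the list alone. Of the 14 lists past the threshold it was the only one whose call held with an estimated correlation. The glycolysis list rose by a median of 0.43 (adjusted p = 1.20e-11, and adjusted p = 0.497 with an estimated correlation), with 19 of 20 members higher, 1 past the threshold and 15 adjusted over the list alone. Among its members, Aldoc differed by 1.27 (SE 0.21), Pgk1 by 0.81 (SE 0.14) and Eno2 by 0.41 (SE 0.07), each short of the threshold over all genes, although Aldoc passed with the replicate number as a block (adjusted p = 0.0427). With sample weights the glycolysis median was 0.28. The 2 lists share no gene, which was fixed when they were written and does not make them separate signals. Slc16a3, named above among the genes that respond to low oxygen, is a member of the glycolysis list.

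Markers of other cell types also moved. The macrophage list was higher by a median of 1.598 (adjusted p = 4.38e-07, and adjusted p = 0.768 with an estimated correlation), with 14 of 14 members higher, 0 past the threshold and 6 adjusted over the list alone. Ptprc, the pan-leukocyte antigen, differed by 2.08 (SE 0.58), Trem2 by 1.84 (SE 0.52), Fcer1g by 1.73 (SE 0.51) and Cd68 by 1.68 (SE 0.48). The inflammasome list, whose genes process interleukin-1, rose with it by a median of 0.43 (adjusted p = 0.0178, and adjusted p = 0.768 with an estimated correlation). None of its 13 members passed over all genes and 2 did adjusted over the list alone. Nlrp1b differed by 1.34 (SE 0.37), Casp1 by 1.33 (SE 0.45), Aim2 by 1.06 (SE 0.29) and Panx1 by 0.43 (SE 0.16). The skeletal muscle list rose by a median of 1.13 (adjusted p = 2.32e-04, and adjusted p = 0.768 with an estimated correlation), with all 8 tested of its 15 members higher, Myh1 by 1.47 (SE 0.46) and Acta1 by 1.45 (SE 0.52). The list mean was only 4.26 to 4.55 in naive libraries, near the filter bound of 3. That filter, on the mean of all libraries, favours genes that are high in the injected ones. The Schwann cell and nerve list rose by a median of 1.06 (adjusted p = 0.00805, and adjusted p = 0.768 with an estimated correlation), with Gap43 at 1.15 (SE 0.55). The adipocyte list fell by a median of 0.39 (adjusted p = 0.00536, and adjusted p = 0.768 with an estimated correlation), with 9 of 11 members lower, among them Cfd at -2.83 (SE 1.03), Adipoq at -2.56 (SE 0.86) and Scd1 at -0.81 (SE 0.16). Adjusted over the list alone, 5 skeletal muscle genes and 1 adipocyte gene passed, and 0 genes of these and the Schwann cell list over all genes. The inflammasome and Schwann cell calls ended without naive 3 (medians 0.41 and 0.37), and that of adipocytes without naive 2 (median -0.30). With the macrophage covariate the medians were 0.08 for the inflammasome list and 0.58 for the Schwann cell list, and both calls were lost, while that of adipocytes was -0.72. Sample weights ended the skeletal muscle (0.64) and Schwann cell (0.44) calls, and with no filter on low values the skeletal muscle median was 0.72.

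A further 7 lists passed, each lost with an estimated correlation (adjusted p = 0.497 for lysosome and autophagy, adjusted p = 0.768 for the others). Lysosome and autophagy genes rose by a median of 0.15 (adjusted p = 0.00242), with the acid hydrolase genes Gla at 0.49 (SE 0.09) and Ctsa at 0.32 (SE 0.11), 2 members past the threshold adjusted over the list alone and 0 over all genes. Cytosolic ribosomal protein genes rose by a median of 0.17 (adjusted p = 0.00229), all 25 members being higher, with Rpl11 at 0.32 (SE 0.11). Immediate early genes rose by a median of 0.46 (adjusted p = 0.0178), with Btg2 at 1.20 (SE 0.44) and Jun at 0.48 (SE 0.19). Mitosis genes rose by 0.35 (adjusted p = 0.0493) with all 24 members higher, but the median was -0.18 without naive 2, and the call was lost without non-primed 2 (0.17) or any 1 primed library (0.35). Interferon-stimulated genes fell by a median of 0.46 (adjusted p = 0.00805) with 23 of 25 lower, including Ifi27l2a at -1.35 (SE 0.79) and Oas2 at -1.08 (SE 0.51), and the median was -0.07 without naive 3 and -0.28 without naive 1, where the call was lost. MHC class I presentation genes fell by 0.24 (adjusted p = 0.0178), with H2-T23 at -0.58 (SE 0.21), and by 0.05 without naive 1, short of the threshold. Cholesterol synthesis genes fell by 0.15 (adjusted p = 0.0493), with the regulator Srebf2 at -0.41 (SE 0.17), stood at 0.08 without naive 3, and lost their call without naive 1 (-0.21), non-primed 2 (-0.11), non-primed 3 (-0.18) or primed 3 (-0.15). Calls were also lost without naive 2 or non-primed 2 for ribosomal proteins (0.10 and 0.06) and without naive 1, naive 2 or non-primed 3 for immediate early genes (0.32, 0.39 and 0.42). Calls that held moved by over 1.5 times without naive 2 for interferon (-0.95) and cholesterol (-0.43), without naive 3 for MHC class I (-0.37) and mitosis (0.67), without naive 1 for mitosis (0.54) and without non-primed 1 for cholesterol genes (-0.27). With the macrophage covariate the calls of lysosome (0.12) and MHC class I genes (-0.23) were lost, interferon (0.20) and cholesterol genes (0.38) turned, and mitosis genes stood at 1.18. For the other 32 tested lists the adjusted p lay between 0.0533 and 0.992.

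Cultures from paws injected on both days differed from naive cultures in 16 genes, 15 higher and 1 lower (limma, adjusted p from 0.0345 upwards). The largest rises were in Npy, which encodes neuropeptide Y (ENSMUSG00000029819, chromosome 6, 49822710 to 49829507), from 6.10 ± 0.24 to 8.02 ± 0.54 (SD, n = 3), a difference of 1.92 (SE 0.25, adjusted p = 0.0464), in Aqp5, a water channel, at 1.63 (SE 0.20), and in Pla1a, a phosphatidylserine-specific phospholipase (ENSMUSG00000002847, chromosome 16, 38396117 to 38433145), at 1.61 (SE 0.15, adjusted p = 0.0345). Eef1a2 rose by 1.42, Car9 by 1.41, Slc16a3 by 1.06, Armh4 by 0.84, Lmcd1 by 0.84, Fam162a by 0.78 and Tmem45a by 0.77. Bnip3 rose by 0.70 and Ndrg1, another gene of the HIF1A target list, by 0.66. Esm1 was the only fall, by 3.16 (SE 0.36, adjusted p = 0.0345). Among the lower genes with the next smallest p-values, not past the threshold, were Sox11 at -1.49 (SE 0.22), Ltbp3 at -0.63 (SE 0.10) and Bcr at -0.48 (SE 0.07). All 16 genes separated the groups without overlap, as did 2679 (17.1%) of the tested genes, where chance gives 10%. Non-primed libraries enter this comparison only through the shared spread and the filter. The number of genes was 0 without primed 2 or any 1 of the non-primed libraries, 1 without primed 3, 58 without primed 1, 56 without naive 1, 356 without naive 2 and 196 without naive 3. It was 0 with no filter, no variance trend, the 2 groups alone or the macrophage covariate, 51 with the replicate number as a block, 13 of them among the 16, without Armh4, Eef1a2 and Fam162a, and 733 with sample weights. With the covariate the differences were 1.51 (SE 0.22) for Pla1a, -3.57 (SE 0.52) for Esm1, 0.97 (SE 0.11) for Lmcd1, 0.73 (SE 0.13) for Bnip3, 1.04 (SE 0.19) for Car9 and 1.41 (SE 0.30) for Npy.

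The HIF1A target list rose by a median of 0.53 (adjusted p = 7.27e-12, and adjusted p = 0.0122 with an estimated correlation), with 19 of 20 members higher, 3 past the threshold and 11 adjusted over the list alone. It was again the only call of the 11 lists past the threshold that held with an estimated correlation. All 20 glycolysis genes were higher, by a median of 0.54 (adjusted p = 3.17e-15, and adjusted p = 0.247 with an estimated correlation), with 1 past the threshold and 16 adjusted over the list alone. Aldoc differed by 1.30 (SE 0.21), Pgk1 by 0.82 (SE 0.14), the glucose transporter Slc2a1 by 0.79 (SE 0.15), Hk2 by 0.65 (SE 0.18) and Ldha by 0.47 (SE 0.12), of which Aldoc passed with the replicate block (adjusted p = 0.0365). Lysosome and autophagy genes rose by a median of 0.23 (adjusted p = 5.08e-06, and adjusted p = 0.187 with an estimated correlation), with 19 of 21 higher and Ctsa at 0.57 (SE 0.11). Fatty acid oxidation genes rose by a median of 0.15 (adjusted p = 0.0331, and adjusted p = 0.795 with an estimated correlation), with Acaa2 at 0.41 (SE 0.10). Ribosomal protein genes rose by 0.16 (adjusted p = 0.00152, and adjusted p = 0.795 with an estimated correlation). Cholesterol synthesis genes fell by 0.41 (adjusted p = 1.95e-04, and adjusted p = 0.795 with an estimated correlation), all 21 being lower, with Srebf2 at -0.61 (SE 0.17). The 7 mitochondrially encoded genes tested fell by a median of 0.39 (adjusted p = 0.0331, and adjusted p = 0.795 with an estimated correlation), with mt-Nd2 at -0.71 (SE 0.31).

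Macrophage genes were again higher, by a median of 1.79 (adjusted p = 7.90e-08, and adjusted p = 0.795 with an estimated correlation), with 14 of 14 members higher, 0 past the threshold over all genes and 11 adjusted over the list alone. Beside them, the complement list rose by a median of 0.33 (adjusted p = 0.0331, and adjusted p = 0.795 with an estimated correlation). Its members with the smallest p-values were Cd59a, an inhibitor of the membrane attack complex, at 0.40 (SE 0.10), and the C1q chains, which macrophages make, C1qa at 2.29 (SE 0.69), C1qb at 2.23 (SE 0.68) and C1qc at 2.22 (SE 0.64), of which C1qb passed with the replicate block (adjusted p = 0.0498). The inflammasome list rose by 0.52 (adjusted p = 0.0142, and adjusted p = 0.740 with an estimated correlation), with Casp1 at 1.31 (SE 0.45) and Nlrp1b at 1.28 (SE 0.37), and 0 members past the threshold. Skeletal muscle genes rose by 1.02 (adjusted p = 6.96e-04, and adjusted p = 0.795 with an estimated correlation). Adjusted over the list alone, 5 lysosome, 2 skeletal muscle and 1 fatty acid oxidation genes passed, and 0 genes of these 3 lists over all genes. Without 1 library, calls were lost for complement (naive 1, naive 3, primed 1 or primed 2; medians 0.22 to 0.42), inflammasome (naive 3 or primed 1; 0.59 and 0.57), fatty acid oxidation (naive 1, naive 3 or primed 1; 0.12 to 0.13), mitochondrially encoded genes (any naive library or primed 2; -0.47 to -0.18), ribosomal proteins (naive 2; 0.12) and cholesterol synthesis (naive 3; -0.13). With the macrophage covariate the medians were -0.18 for complement, 0.07 for inflammasome and 0.21 for cholesterol synthesis genes, and the calls of mitochondrially encoded (-0.34) and fatty acid oxidation genes (0.11) were lost. Sample weights ended the calls of complement (0.35), inflammasome (0.34) and fatty acid oxidation (0.10). Calls that held moved by over 1.5 times for skeletal muscle without primed 3 (0.67) or with no filter on low values (0.64), for cholesterol without naive 2 (-0.68), primed 1 (-0.67) or primed 2 (-0.25), for mitochondrially encoded genes without primed 1 (-0.61) and for ribosomal proteins without naive 3 (0.25), primed 1 (0.25) or primed 2 (0.10) or with quantile normalization (0.09). For the other 35 tested lists the adjusted p lay between 0.0542 and 0.983.

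**Figure D3:**
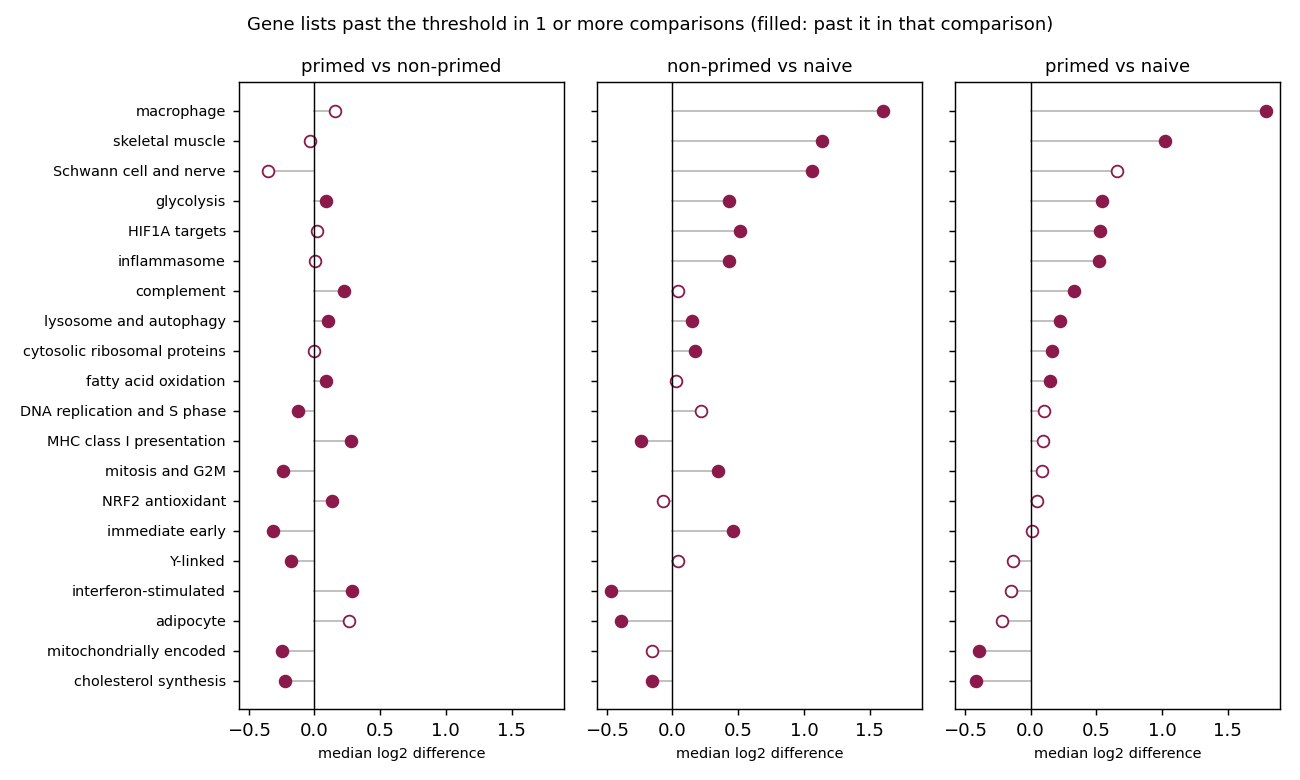
Median log2 difference (x axis) of each of the 20 gene lists past the threshold in 1 or more comparisons (y axis), in a panel per comparison. Filled points passed the camera test with the preset correlation and open points did not. HIF1A targets lie at 0.51 and 0.53 against naive libraries and at 0.02 between primed and non-primed libraries.

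Of the genes called against naive libraries, 10 were called for both injected groups, in the same direction, namely Pla1a, Atp6v1b2, Fuca2, Tmem45a, Slc16a3, Car9, Aqp5, Lmcd1, Bnip3 and Esm1. Atp6v1b2 and Fuca2, outside the naming rule, are named after their values were seen. Among higher genes, 9 were shared by lists of 18 and 15, where independent lists would share 0.0173, and simulated unchanged groups shared 0.1 genes on average and at most 2 over both directions. The log2 differences of the 2 comparisons correlated across genes at r = 0.92, against 0.81 in the simulations, where the shared naive libraries alone produce a correlation. The covariance was 0.14 against 0.07 simulated, a difference of 0.07, and 3 naive libraries cannot be split so that each part keeps a pair, so part of the excess may come from the shared controls. Genes are not independent replicates in these values. The simulations drew genes independently and did not link same-numbered primed and non-primed libraries. Genes that deviate together in a naive library, or linked pairs, can raise the correlation, covariance and overlap without any change. The excess over the simulations therefore does not by itself show a shared response. Any difference among the 3 groups passed for 11 genes (limma F test, smallest adjusted p = 0.0395), a number that was 11 with the replicate block, with 2 genes shared, 0 without any 1 non-primed library or primed 2, 2 without primed 3, 34 without primed 1, 217 without naive 2 and 103 without naive 3.

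Between primed and non-primed cultures, 0 of 15623 genes passed the threshold (limma, smallest adjusted p = 1.00), and 197 genes (1.26%) had an unadjusted p below 0.05, 89 higher and 108 lower in primed cultures. That share is below the 0.05 of unchanged groups. The fit shares its spread with the naive libraries, whose median SD was 0.22 against 0.10 and 0.14, so this test is conservative. For the comparisons with naive libraries the sharing works the other way and tends to make the SE too small. Their calls are therefore less certain than the adjusted p-values show. A fit of primed and non-primed libraries alone with the replicate block also gave 0 genes. With 3 libraries per group, 0 calls do not show that priming had no effect. The groups did not overlap for 1806 genes (11.6%), where chance gives 10%. The smallest p-values among higher genes, none past the threshold, belonged to Gstt1, a glutathione transferase, at 0.37 (SE 0.08), Calcoco1 at 0.26 (SE 0.07), Fggy at 0.48 (SE 0.13), Cox4i2, a cytochrome c oxidase subunit, at 0.49 (SE 0.14) and Pltp, the phospholipid transfer protein gene, at 0.42 (SE 0.12). Among lower genes they belonged to Tex10 at -0.28 (SE 0.08), Camk2b at -0.34 (SE 0.11), Snora41 at -0.44 (SE 0.15), Zfp959 at -0.53 (SE 0.18) and Myef2 at -0.29 (SE 0.10). C3, the central complement component (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136), averaged 11.32 ± 0.58 in primed and 10.79 ± 0.17 in non-primed libraries (SD, n = 3), a difference of 0.53 (SE 0.48), with primed 1 at 11.98 and primed 2 and primed 3 at 11.08 and 10.90. With sample weights, which gave 10.4 to non-primed 1 and 7.29 to primed 3, 2109 genes passed, 884 higher and 1225 lower.

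Small shifts were shared by the genes of 13 lists, 7 higher and 6 lower in primed cultures, and 0 of them passed with an estimated correlation. No member of these lists passed over all genes or adjusted over the list alone. MHC class I presentation genes rose by a median of 0.28 (adjusted p = 5.60e-07, and adjusted p = 0.854 with an estimated correlation), all 12 being higher, with H2-T23 at 0.48 (SE 0.21), H2-D1 at 0.41 (SE 0.19) and H2-K1 at 0.39 (SE 0.15), genes similar enough in sequence to share reads. NRF2 antioxidant genes rose by 0.13 (adjusted p = 2.13e-06, and adjusted p = 0.338 with an estimated correlation), with 17 of 19 higher, Gstm1 at 0.51 (SE 0.22), whose paralogs may share its reads, the catalase gene Cat at 0.23 (SE 0.09), Srxn1 at 0.15 (SE 0.07) and Sod1 at 0.14 (SE 0.07). Glycolysis genes rose by 0.09 (adjusted p = 0.00108, and adjusted p = 0.937 with an estimated correlation), with Gpi1 at 0.21 (SE 0.11) and Pfkm at 0.16 (SE 0.07). Interferon-stimulated genes rose by 0.28 (adjusted p = 0.00380, and adjusted p = 0.982 with an estimated correlation), all 25 being higher, with Irf7 at 0.62 (SE 0.50) and Oas3 at 0.56 (SE 0.36). Their list mean was 9.02 in primed 1 and 9.38 in primed 2. In primed 3 it was 8.52, below the 8.57 to 8.85 of non-primed libraries. Complement genes rose by 0.23 (adjusted p = 0.00666, and adjusted p = 0.937 with an estimated correlation), with 19 of 20 higher, among them C2 at 0.39 (SE 0.24), C1ra at 0.28 (SE 0.19), Serping1 at 0.27 (SE 0.16) and C1s1 at 0.25 (SE 0.24). Fatty acid oxidation genes rose by 0.09 (adjusted p = 0.00635, and adjusted p = 0.744 with an estimated correlation), with Acaa2 at 0.23 (SE 0.10). Lysosome and autophagy genes rose by 0.10 (adjusted p = 0.00415, and adjusted p = 0.744 with an estimated correlation), with Ctsd at 0.33 (SE 0.20) and Ctsa at 0.25 (SE 0.11).

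Lower in primed cultures were the immediate early genes, by a median of 0.31 (adjusted p = 4.02e-05, and adjusted p = 0.937 with an estimated correlation), with Egr1 at -0.83 (SE 0.34), Junb at -0.54 (SE 0.32) and Egr3 at -0.37 (SE 0.15). The list mean was 8.31 in primed 1 and 8.69 in primed 2. In primed 3 it was 9.31, above the 8.94 to 9.23 of non-primed libraries. Cholesterol synthesis genes fell by 0.23 (adjusted p = 0.00141, and adjusted p = 0.982 with an estimated correlation), with Idi1 at -0.50 (SE 0.39). Their list mean in primed 1 was 9.61, above the 9.24 to 9.51 of non-primed libraries. All 24 mitosis genes and 22 of 23 S phase genes were lower, by medians of 0.24 (adjusted p = 0.00582) and 0.13 (adjusted p = 0.0303), with adjusted p = 0.982 for each with an estimated correlation, Kif11 at -0.45 (SE 0.42) and Hells at -0.55 (SE 0.31). The mitochondrially encoded genes fell by 0.25 (adjusted p = 0.00635, and adjusted p = 0.937 with an estimated correlation), with mt-Nd2 at -0.43 (SE 0.31). The 4 Y-linked genes fell by 0.18 (adjusted p = 0.0215, and adjusted p = 0.880 with an estimated correlation), with Eif2s3y at -0.26 (SE 0.10). Without primed 2, the number of lists was 7. The calls lost then were those of complement (median 0.02), interferon (0.10), lysosome (0.05), cholesterol (-0.08), mitosis (-0.20), mitochondrially encoded (-0.09) and Y-linked genes (-0.09). Without primed 1, those of interferon (0.23), fatty acid oxidation (0.07) and immediate early genes (-0.12) were lost, and without non-primed 2 those of mitosis (-0.04), S phase (-0.05) and lysosome genes (0.08). Without primed 3, those of cholesterol (-0.17) and S phase genes (-0.10) were lost, without non-primed 1 that of mitochondrially encoded genes (-0.23), and without non-primed 3 those of mitochondrially encoded (-0.14) and Y-linked genes (-0.10). With sample weights the medians were 0.10 for MHC class I, 0.14 for complement, 0.02 for lysosome, -0.06 for interferon, -0.13 for Y-linked and 0.05 for immediate early genes, all without a call, and -0.43 for cholesterol synthesis genes, with the call kept. Calls that held moved by over 1.5 times for glycolysis without non-primed 1 (0.06), for complement without non-primed 1 (0.13), non-primed 3 (0.15) or primed 3 (0.38), for interferon without primed 3 (0.47), for fatty acid oxidation without primed 2 (0.06), for cholesterol without non-primed 1 (-0.15) or primed 1 (-0.44), for mitochondrially encoded genes without non-primed 2 (-0.38) or primed 1 (-0.45), for S phase (-0.20) and mitosis (-0.39) without non-primed 3, and for immediate early genes without primed 3 (-0.55). With the macrophage covariate complement stood at 0.11 and S phase at -0.09, the latter without a call. For the other 33 tested lists, among them HIF1A targets (adjusted p = 0.499) and macrophages (adjusted p = 0.499), the adjusted p lay between 0.0612 and 0.979. With the replicate number as a block the NF-kB list also passed (median 0.07, adjusted p = 0.0418, and adjusted p = 0.940 with an estimated correlation), and with the block in primed and non-primed libraries alone so did NF-kB (adjusted p = 0.0472), adipocyte (median 0.26, adjusted p = 0.00114) and macrophage genes (median 0.16, adjusted p = 0.0443). None of these 3 passed with an estimated correlation in that fit (adjusted p = 0.864, adjusted p = 0.864 and adjusted p = 0.912 with an estimated correlation).

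Complement receptor and inflammasome genes fixed in advance had larger estimated differences between naive and injected cultures than between the injected groups, a contrast that was not tested, and none passed the threshold in the fit of all libraries without a block. C3ar1, a receptor for the C3a fragment, averaged 7.38 ± 1.46 in naive, 9.04 ± 0.27 in non-primed and 9.11 ± 0.55 in primed libraries (SD, n = 3). Its difference from naive was 1.66 (SE 0.63, adjusted p = 0.259) in non-primed and 1.74 (SE 0.63, adjusted p = 0.231) in primed cultures, and 0.07 (SE 0.63) separated the injected groups. Nlrp3 was at 4.45 ± 0.89, 5.58 ± 0.63 and 5.69 ± 0.77 in the same order, and with the replicate block its difference of 1.24 between primed and naive cultures passed (adjusted p = 0.0467). Naive 2 had C3ar1 at 9.06 and Nlrp3 at 5.48, within the range of the injected libraries, as it had for the macrophage mean. Il1b was at 0.79 to 1.56 in all libraries and was not tested. Pdpn, a marker of activated synovial fibroblasts, was 0.56 (SE 0.10, adjusted p = 0.0815) higher in non-primed and 0.47 (SE 0.10, adjusted p = 0.110) higher in primed than in naive cultures. C3 was 1.35 (SE 0.48, adjusted p = 0.240) and 0.82 (SE 0.48, adjusted p = 0.413) lower than in naive cultures, where naive 2 stood at 13.31. Mtor, Thy1, Cd34, Pdgfra, Prg4, Il6, Cxcl1, Ccl2, Mmp3, Mmp13 and Cfb also missed the threshold in all 3 comparisons. The fibroblast list (adjusted p = 0.81 between the injected groups), and those of lining and sublining fibroblasts, chondrocytes, osteoblasts, tendon, osteoclasts, endothelium, pericytes and keratinocytes, passed in no comparison.

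**Figure D4:**
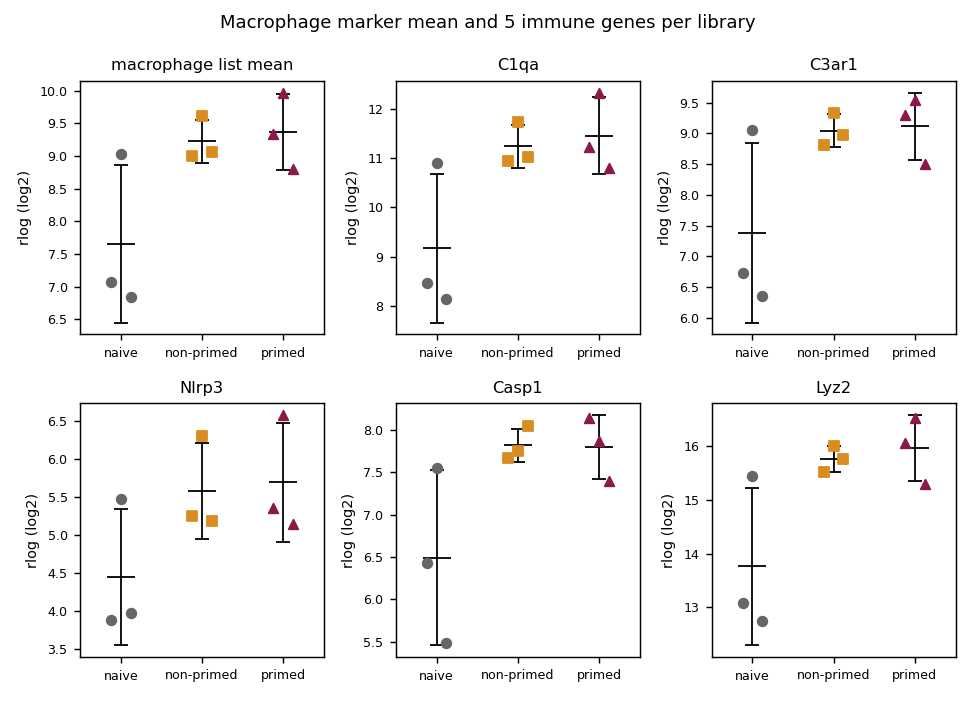
Rlog values (log2, y axis) of the mean of the 14 tested macrophage markers and of C1qa, C3ar1, Nlrp3, Casp1 and Lyz2 in the 3 groups (x axis). Points are libraries, with the mean and SD (n = 3) in black. Naive 2, at 9.04 for the marker mean, lies with the injected libraries in the panel of that mean, and the other naive libraries lie at 7.07 and 6.84.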

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

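The macrophage covariate and the block over the injected groups alone were chosen after the data were seen, the other alternatives before. The count of 0 genes between primed and non-primed cultures held under every alternative run except sample weights, which gave 2109 genes. The 22 genes of non-primed against naive became 0 with no filter on low values, 5 without a variance trend, 13 with a robust prior, 621 with sample weights, 7 with the 2 groups alone and 0 with the macrophage covariate. The 16 genes of primed against naive became 0 with no filter, 0 without a trend, 733 with sample weights, 51 with the replicate block, 0 with the 2 groups alone and 0 with the covariate. The 11 genes of the 3-group test became 0 with no filter, 2 with quantile normalization, 0 without a trend, 2485 with sample weights and 0 with the covariate. The correlation of the differences from naive moved from 0.92 to 0.886 with sample weights and 0.941 with the covariate. More genes enter the adjustment without a filter (27757), and fewer samples estimate the spread in the fit of 2 groups. Against naive, that fit also drops the injected group not compared, whose smaller spread lowers the shared one. For the other settings the cause was not tested.

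Leaving out each library in turn gave 0 to 355 genes for non-primed against naive, 0 to 356 for primed against naive, 0 to 217 for the 3-group test, 7 to 15 lists between the injected groups and a correlation of 0.876 to 0.939. With an estimated correlation, 0 lists passed between the injected groups, 1 in non-primed against naive and 1 in primed against naive. The median of the interferon list between the injected groups turned to -0.0592 and that of immediate early genes to 0.0524 with sample weights. These weights also ended mitosis (0.17) and cholesterol synthesis (0.01) in non-primed against naive, with inflammasome at 0.28, lysosome at 0.25 and MHC class I at -0.48, and gave 1.599 for skeletal muscle in primed against naive. In non-primed against naive, leaving out a library gave -0.18 to 0.67 for mitosis and -0.427 to 0.0806 for cholesterol synthesis. With the macrophage covariate, interferon (0.20) and cholesterol synthesis (0.38) reversed in non-primed against naive, and complement (-0.18) and cholesterol synthesis (0.21) in primed against naive. Calls of S phase and Y-linked genes between the injected groups ended with no filter, and those of mitochondrially encoded and Y-linked genes in the fit of these groups alone. Against naive, no trend ended mitosis and cholesterol in non-primed and fatty acid oxidation in primed cultures, a higher filter and the fit of 2 groups ended mitosis, and both other scalings ended cholesterol in non-primed cultures. None of the 569 refits of named genes past the threshold changed sign. For most refits this was fixed in advance, so it is no evidence of robustness. The groups of these genes did not overlap, so leaving out a library cannot turn the sign, and several other settings leave the group means unchanged. The replicate block left 0 genes between primed and non-primed cultures (0 also in a fit of these groups alone), ended no list call there and added NF-kB, and in the fit of these groups alone also adipocyte and macrophage lists, to give 14 and 16 lists. Against naive, whose libraries the numbers did not pair, it gave 17 genes for non-primed cultures, 5 of them among the 22, with Esm1 and Slc16a3 at adjusted p = 0.0501, and 13 of the 51 for primed cultures were among the 16. It ended the mitosis call in non-primed cultures (adjusted p = 0.0684), added the chemokine list there (adjusted p = 0.0261), and in primed cultures added chemokines (adjusted p = 0.0231), matrix proteases (adjusted p = 0.0443) and Schwann cells (adjusted p = 0.0477). These added lists had adjusted p from 0.670 to 0.802 with an estimated correlation. Named genes that passed with it and not in the fit of all libraries without a block were Aldoc in both comparisons, and Nlrp3 and C1qb in primed cultures. In the 3-group test it gave 11 genes, 2 of them shared. The robust prior has no camera counterpart, so it gave no value for the lists. Depth is unknown, so what it limits could not be assessed.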

Other observations

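Tests of macrophage RNA, of scaling and of variation within the primed group were chosen after the result was seen, those that regroup the libraries before. The naive cultures differed from each other in markers of several cell types. Adipocyte genes were high in 2 of them: Adipoq was at 8.64 in naive 1 and 8.46 in naive 2 against 5.44 in naive 3 and 4.30 to 6.56 in injected libraries, and Plin1 at 6.55 and 6.58 against 3.18 to 4.62 elsewhere. Naive 3 had the highest mean of contractile genes, 11.32 against 9.13 to 10.68, the highest mean of cholesterol synthesis genes, 10.15 against 8.84 to 9.61, and the lowest mean of Schwann cell genes, 7.35 against 8.39 to 9.38. Naive 2 had the lowest mean of mitosis genes, 7.87 against 8.89 to 9.63, and the highest mean of tendon genes, 9.93 against 8.95 to 9.49. These libraries and genes were chosen after their values were seen.

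C3ar1, C5ar1, Nlrp3, Pycard and Casp1 were higher in injected than in naive cultures, with a median of 1.19 over the 10 differences. A hypothesis is that macrophages carried through culture contribute this RNA, since Lyz2 was at 12.75 and 13.09 in naive 3 and naive 1 but 15.30 to 16.53 in the other libraries, and none of the 5 genes is in the macrophage list. With the macrophage mean as a covariate the median became -0.156, and 2 of the 10 differences lay beyond 2 SE, against 8 before. Those 2 were of C5ar1, which turned to -0.87 and -0.82. Only naive 2 among naive libraries had a high marker mean. Although not injected, it lay within the range of the injected libraries for all 5 genes, with C3ar1 at 9.06 and Casp1 at 7.56. Naive 1 and naive 3 lay below that range for all 5. With 1 such library, macrophage content and injection are only weakly told apart for these genes. Induction of these genes in fibroblasts by the crystals stays open as a biological explanation, untested.

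Glycolysis and HIF1A target genes were higher in injected cultures, and neither the macrophage covariate nor quantile normalization removed this. With the macrophage covariate the lower of the 2 medians against naive was 0.487 for glycolysis (0.430 before) and 0.460 for HIF1A targets (0.513 before), and after quantile normalization 0.415 and 0.488, with both lists past the threshold at the preset correlation. The glycolysis call is lost with an estimated correlation (adjusted p = 0.497 and adjusted p = 0.247 with an estimated correlation), so only the medians bear on that list. Only naive 2, with a macrophage mean of 9.04, parts macrophage content from injection. Its HIF1A target mean was 11.58 against 11.95 to 12.05 in injected libraries, and its glycolysis mean 11.92 against 12.36 to 12.55. Resting on 1 library, this argues only weakly against macrophage RNA as the whole cause. Library medians already lay at 8.78 to 8.83, so the scaling test could hardly have come out otherwise. Single genes lost their calls with the covariate, in non-primed against naive with SEs that grew, Car9 going from 1.22 (SE 0.17) to 0.89 (SE 0.18), Slc16a3 from 1.03 (SE 0.12) to 0.96 (SE 0.17) and Bnip3 from 0.76 (SE 0.09) to 0.78 (SE 0.13). A lasting effect of the injection is a hypothesis only, since a difference in cell density, oxygen or culture date between naive and injected cultures may do the same and no label records it.

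MHC class I genes were higher in primed than in non-primed cultures. With the macrophage covariate the median was 0.275 (0.281 before) and the list stayed past the threshold at the preset correlation, though not with an estimated one (adjusted p = 0.854 with an estimated correlation before the covariate). The macrophage list differed between these groups by a median of only 0.16, so the covariate could hardly have changed the value. This test therefore does not decide whether macrophage RNA adds to the rise. Variation between cultures may account for it: the lowest primed library, primed 3, had a list mean 0.03 below the highest non-primed library (a gap of -0.0296), while primed 1 and primed 2 lay at 11.10 and 11.07. Naive libraries ranged from 10.70 to 11.24. An effect of priming stays open.

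Regrouping the libraries bears on the counts. For the 3-group test, 4 of 100 splits drawn from 280, the real one included, gave 11 genes or more, a share under 0.05. The splits exchange libraries freely and so ignore the pairs, and the highest other split gave 125. All 4 kept the naive libraries together, as 6 of the 100 did, so this bears on naive against injected libraries and not on primed against non-primed. Among those 6 the real split did not stand out, so chance is not excluded. Of the 49 splits that part all 3 same-numbered pairs of primed and non-primed libraries, the real one had 11 genes and the highest other 9. Splits that broke up the naive libraries gave 0 genes or 1, so most of the 49 could not compete. The rank therefore rests on 11 genes against 9 in the few splits that kept the naive libraries together, and is no support for the real grouping. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Between primed and non-primed all 10 gave 0 genes, and 4 gave at least the real 13 lists, with 16 at most elsewhere. Among the 3 other splits that part all 3 same-numbered pairs, the lists numbered 16, 4 and 9. With sample weights, 1 of 10 splits gave 2109 genes and the highest other 457. The weights are estimated from 9 libraries and reached 10.4 for 1 of them, so these counts are uncertain, and in 2 of the 10 fits, both with 0 genes, the estimation of weights stopped before converging. For non-primed against naive, 1 of 10 gave 22 genes (highest other 0) and 5 gave 14 lists or more (highest other 15). For primed against naive, 2 of 10 gave 16 genes or more and 9 gave 11 lists or more (highest other 22). The highest other gene count was 124, from primed 1 grouped with naive 1 and naive 2, several times the real count. What produces that count was not tested.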
